A study of Homo sapiens with 8 samples.

How the data were processed

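Total RNA from 8 cultures of hTERT-RPE1 cells was sequenced after library preparation by Illumina protocols, per the labels. Cells grew for 2 days in complete medium, were washed with saline and were placed in serine/glycine-free medium for 8 h. Whether the complete-medium cultures had the same wash and medium change is not given in the sources used here. Groups and replicate numbers came from the sample titles, and the series text states that equal numbers mark the same batch of treated cells.

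The authors deposited FPKM values in 2 tables, 1 per batch, each with 57884 Ensembl genes and 4 libraries. TopHat, Cufflinks, Cuffdiff and the hg19 build are named in the submitters' processing notes, and their versions and settings are not given in the sources used here. FPKM divides by transcript length and library size, so short RNAs with few reads take large values. Small RNA genes, counted together with rRNA genes and mitochondrial rRNA and tRNA genes, held over 60% of each FPKM sum. The tables were normalized separately, and groups were therefore compared within a batch. An exact 0 can be a failed estimate. Of the listed genes, 33180 share their locus with another and 2263 share a symbol, so reads of overlapping genes and near-identical copies, such as HSPA1A and HSPA1B or the metallothioneins, may have been split between them. Loci are hg19, written 1-based. Gene types came from GENCODE 29 by Ensembl ID, which 95.8% of tested genes matched, and no GENCODE coordinates were used.

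Genes with FPKM of 1 or more in at least 2 libraries were kept, 17994 in all, of which 13080 are protein-coding. Tests used log2(FPKM + 1), so fold changes understate those of low genes. Limma 3.58.1 in R 4.3.3 fitted 4 group means with the batch as a block, with a trended empirical Bayes prior and two-sided p-values adjusted by Benjamini-Hochberg over all genes tested (threshold 0.05). This left 3 residual and 2.97 prior degrees of freedom. The limma p-values rest on 2 independent experiments. Because the labels state that numbers mark a shared batch, the block pairs the libraries. Deviations from group means of same-numbered libraries correlated at 0.650 to 0.775 in 12 pairs. With 2 libraries per group the pairs of batch 2 repeat those of batch 1. Any difference between the 2 tables would give such correlations, so they do not show shared treated cells.

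Gene lists fixed before the data were examined were tested with camera at a preset correlation of 0.01, adjusted over the 32 lists tested in each comparison. Camera with an estimated correlation and fry stand beside it, and members were also adjusted over the list alone. No list was called with an estimated correlation, also where that correlation lay below the preset, as for serine synthesis (−0.157). That setting tests each list on the 3 residual degrees of freedom, where few calls are within reach. A call lost there does not by itself show that members moving together made it. The preset tests on nearly as many degrees of freedom as genes, taking them as nearly independent. Its p-values therefore do not measure how a list varies between the 2 experiments. Immune markers had 1 measured member and were not tested. In wild type the other lists not called had adjusted p from 0.0651 (mitosis) to 0.805 (nucleotide synthesis).

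The rule for named genes, also fixed before the data were examined, takes ATF3, the serine synthesis genes, up to 8 called genes per direction and comparison with the same sign in both batches (where none passed, the 3 with the smallest p), and up to 4 members per list with the smallest p. That rule names 642 gene and comparison pairs. The text draws on 167 of them, the 2 members with the smallest p of each called list (4 for the ATF4 list) beside the called genes, ATF3 and the serine synthesis genes; this narrowing was made after the data were seen, and not every gene it leaves is reported here. CDH1, ESRP1, SPARC, VIM and other genes that set the batches apart were likewise picked after their values were seen.

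The steps were tested on simulated data built from the real batch means and residual spreads of 17994 genes, with 200 genes changed in the wild-type response. Of genes changed by a log2 fold change of 1, 5.0% were called, with a mean estimate of 0.96, and of those changed by 2, 42.0%, with a mean estimate of 1.98; 2 unchanged genes were called. A list of changed genes was called and 0 of 20 unchanged lists were. The simulated noise was independent between genes and the unchanged lists were random genes. False calls of lists whose members move together were thus not tested, and the epithelial list, for example, had an estimated correlation of 0.762. Single genes changed by a log2 fold change of 1 thus mostly miss the threshold here.

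Alternatives varied the pseudocount, filter, scaling, block, prior and libraries used. Those with protein-coding genes only, with a block per genotype and batch, and without both batch 2 libraries labelled knockout were chosen after seeing the data. The tables hold no comparison columns, so a planned count of the authors' own calls was not made.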

Results

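The data are RNA sequencing profiles of hTERT-RPE1 cells, a human retinal pigment epithelial line immortalised with telomerase. Cells with ATF3 intact or labelled ATF3 knockout were kept in complete medium or in medium lacking serine and glycine for 8 h. ATF3 is a stress-induced transcription factor of the ATF/CREB family. The 4 groups hold 2 libraries each, 8 in all, and each replicate number marks 1 of 2 independent experiments (batches). Expression is in FPKM, and 17994 of the 57884 listed genes were tested. Absolute depth is unknown; the commonest step between low values puts the relative depth of the libraries between 1.00 and 1.27 times that of the wild-type complete library of batch 1. FPKM sums ran from 2429662 to 3148153, of which 60.5% to 65.6% lay in small RNA genes, with rRNA and mitochondrial rRNA and tRNA genes counted among them. Libraries of the same batch correlated at r = 0.920 to 0.957 across genes and libraries of different batches at r = 0.768 to 0.815, genes not being independent replicates. Of protein-coding genes, 54 were at 10 FPKM or more in all batch 1 libraries and below 0.5 in all batch 2 libraries, and 32 the reverse. The labels name 1 line for both batches. Whether the same clones, or the same line, were used is not settled here, and every n = 2 value below spans this difference; if 1 batch were another line, each would join 2 lines. Gene lists are called below by camera with its preset correlation. With an estimated correlation, which tests on 3 residual degrees of freedom, 0 lists were called in any comparison.

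ATF3 (ENSG00000162772, hg19 chromosome 1, 212738676 to 212794119, a locus shared by 2 listed genes) was measured first, since it is the gene the genotype label names. In batch 1 it stood at 3.47 FPKM in wild-type complete medium and 6.46 in serine/glycine-free medium, against 3.38 and 4.45 in the libraries labelled knockout. In batch 2 it stood at 3.65 and 18.0 in wild type, against 20.8 and 57.3 in the libraries labelled knockout. Its mRNA was thus lower in the libraries labelled knockout in batch 1, by little in complete medium, and higher there in batch 2, and it was present in each of them. The sources used here do not describe the allele, and a gene-level FPKM does not show whether a transcript encodes protein, so the genotype is given below as labelled.

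**Figure D1:**
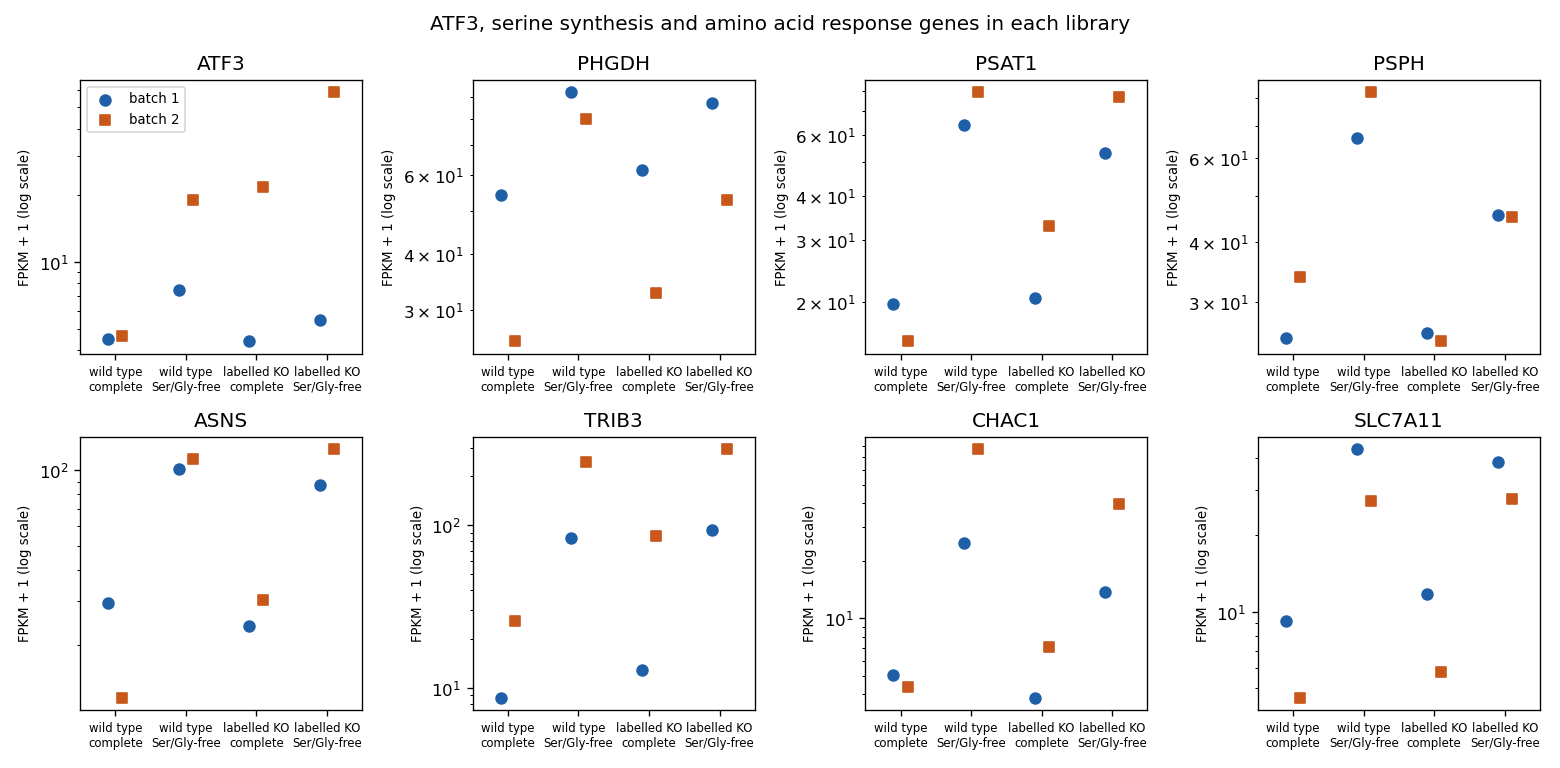
FPKM + 1 on a log axis for ATF3, the serine synthesis genes and amino acid response genes, 1 point per library, with the group on the horizontal axis and the batch as colour and shape. ATF3 reached 57.3 in the serine/glycine-free library labelled knockout of batch 2, while TRIB3 lay higher in serine/glycine-free than in complete medium in each genotype and batch.

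The first comparison asks how wild-type cells respond to loss of serine and glycine. Genes of the amino acid response driven by the transcription factor ATF4 were higher as a group after 8 h, with a median log2 fold change of 1.41 over 37 measured members, a call lost with an estimated correlation (camera adjusted p = 0.179). Of these, 35 were higher in both batches, 26 passed when adjusted over the list alone and 1 passed over all genes tested. SLC7A11, the cystine/glutamate antiporter subunit (ENSG00000151012, chromosome 4, 138948576 to 139163503), rose from 8.20 to 42.5 FPKM in batch 1 and from 3.59 to 26.1 in batch 2, a log2 fold change of 2.40 ± 0.21 (SE, n = 2 per group; limma adjusted p = 0.0462). That call was lost in 17 of 23 alternatives, while the log2 fold change lay between 2.27 and 2.60 in all of them. TRIB3, a pseudokinase induced by ATF4, had a log2 fold change of 3.27 ± 0.32 (adjusted p = 0.0636). PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, had 2.35 ± 0.21 (adjusted p = 0.0545), and CEBPG had 1.52 ± 0.16 (adjusted p = 0.0875).

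The 3 enzymes of serine synthesis were also higher as a group in wild type, with a median of 1.33, and all 3 passed when adjusted over the list alone though none over all genes. PHGDH, the first enzyme of the pathway, went from 53.2 to 90.9 FPKM in batch 1 and from 24.5 to 79.3 in batch 2. PSAT1 went from 18.6 to 62.9 and from 14.4 to 78.3, and PSPH from 24.3 to 65.1 and from 32.8 to 81.2. Camera gave adjusted p = 9.37e-38 for the ATF4 list and 2.18e-07 for serine synthesis, but adjusted p = 0.179 for both with an estimated correlation. The small values take genes as nearly independent and do not measure how a list varies between the batches. Fry, which tests whether members move one way, gave adjusted p = 0.0277 for both.

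Other lists called higher in wild type were aminoacyl-tRNA synthetases (median 0.69, 12 of 20 adjusted over the list alone), inflammatory NF-kappaB targets (0.69), amino acid transport (0.35), MYC and ribosome biogenesis genes (0.31), glutathione metabolism (0.26), AP-1 immediate early genes (0.26), p53 targets (0.24), proline, asparagine and glutamate synthesis (0.21), serine, glycine and folate metabolism (0.17) and cytosolic ribosomal proteins (0.12). Lists share members, such as SLC7A11 (ATF4 and amino acid transport lists) and MYC (AP-1 and MYC lists), so their calls are not independent. SARS, which charges tRNA with serine, had a log2 fold change of 1.48 ± 0.15, and WARS had 1.18 ± 0.14. MTHFD2, a mitochondrial folate enzyme, had 2.11 ± 0.31, and ASNS, asparagine synthetase, 2.47 ± 0.42. The leading members of the glutathione list were CHAC1, which degrades glutathione (3.22 ± 0.46), and CTH (1.68 ± 0.29). Those of the p53 list were SESN2 (2.84 ± 0.44) and GADD45A (1.03 ± 0.20), which other stresses also induce. With an estimated correlation the adjusted p of these lists lay between 0.196 and 0.665. Leaving out 1 wild-type library ended the call of the cytosolic ribosomal list (complete, either batch, adjusted p = 0.153 and 0.138; serine/glycine-free of batch 1, 0.896), the folate list (complete or serine/glycine-free of batch 1, 0.0540 and 0.0619), the p53 list (serine/glycine-free of batch 1 or complete of batch 2, 0.529 and 0.713), the AP-1 list (complete or serine/glycine-free of batch 2, 0.546 and 0.410) and the NF-kappaB and proline lists (serine/glycine-free of batch 2, 0.0711 and 0.0553). The ribosomal and AP-1 lists were also lost without either serine/glycine-free library labelled knockout (adjusted p 0.0507 to 0.0524), and the p53 list without that of batch 1 (0.0505). Over all alternatives the ribosomal call was lost in 11 of 23, the AP-1 call in 9 and the p53 call in 7.

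Lists called lower in wild type were cholesterol synthesis (median −0.55), mitochondrially encoded genes (−0.35), hypoxia genes (−0.30), fatty acid synthesis (−0.25), DNA replication (−0.25) and glycolysis (−0.21). MVD of cholesterol synthesis had a log2 fold change of −1.01 ± 0.15, FASN, the fatty acid synthase, −0.86 ± 0.24, and PFKFB4 −1.54 ± 0.27. Within the hypoxia list VEGFA went the other way, at 1.14 ± 0.38. None of these members passed over all genes, and with an estimated correlation the adjusted p of these lists lay between 0.285 and 0.665. Leaving out the wild-type complete library of batch 1 ended the calls of fatty acid synthesis (adjusted p = 0.0814) and hypoxia genes (0.495), and leaving out that of batch 2 those of DNA replication (0.170) and glycolysis (0.0716); the hypoxia list changed direction without the wild-type serine/glycine-free library of batch 2 (0.977).

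Over all genes, limma called 7 genes higher and 3 lower in wild type at adjusted p under 0.05, with 1014 at an unadjusted p under 0.05 where 899.7 are expected by chance. SLC7A11 was the only protein-coding gene among them. The others were RNAs listed at exactly 0 in both libraries of 1 of the 2 groups, among them AC118344.1, RNU6-1024P and U3, for which no fold is given. With protein-coding genes only there were 5 higher and 1 lower, and 52 higher and 6 lower with a block per genotype and batch as well, both alternatives chosen after seeing the data. The main fit leaves any genotype difference that varies with batch in its spread, which can widen the errors of this response. The number of genes called thus depends on the block and on the genes tested. Reassigning the batch 2 values of each short noncoding gene to the libraries at random gave a median of 23 calls over the 5 comparisons, against 28 observed. The SLC7A11 call was lost when any 1 of the 8 libraries was left out (adjusted p 0.0936 to 0.505) though its log2 fold change stayed between 2.27 and 2.54, and its adjusted p ranged from 0.00936 to 1 over all alternatives. With 1 library left out there were 6 to 11 genes higher and 2 to 9 lower, the most higher without the wild-type complete library of batch 1 and the most lower without that of batch 2.

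The second comparison asks the same of the cells labelled knockout. The ATF4 list was again higher as a group, with a median of 0.97, though not with an estimated correlation (camera adjusted p = 0.236); 35 of 37 members were higher in both batches, 23 passed when adjusted over the list alone and 0 over all genes. TRIB3 went from 11.8 to 93.1 FPKM in batch 1 and from 84.7 to 295 in batch 2, a log2 fold change of 2.33 ± 0.32, and SLC7A11 had 1.98 ± 0.21 (adjusted p = 0.172). The serine synthesis list had a median of 0.84, with PSAT1 at 1.30 ± 0.27, PSPH at 0.84 ± 0.18 and PHGDH at 0.60 ± 0.24, all 3 passing over the list alone. Camera gave adjusted p = 2.68e-28 and 6.07e-05 for these lists, but adjusted p = 0.236 for both with an estimated correlation and 0.0382 for both by fry.

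Aminoacyl-tRNA synthetases (median 0.57), inflammatory NF-kappaB targets (0.66), MYC and ribosome biogenesis genes (0.39), proline, asparagine and glutamate synthesis (0.29), AP-1 genes (0.28), histones (0.28), serine, glycine and folate metabolism (0.23), amino acid transport (0.19), glutathione metabolism (0.11), cytosolic ribosomal proteins (0.10) and p53 targets (0.10) were called higher. Cholesterol synthesis (−0.69), fatty acid synthesis (−0.34), mitochondrially encoded genes (−0.31), hypoxia genes (−0.24), DNA replication (−0.21), glycolysis (−0.19) and mitosis genes (−0.18) were called lower. SARS had a log2 fold change of 1.37 ± 0.15, WDR43 of ribosome biogenesis 0.98 ± 0.21 and CDC20 of mitosis −0.59 ± 0.21. With an estimated correlation the adjusted p of all these lists lay between 0.236 and 0.626. The histone list had batch medians of −0.10 and 0.66 and the glycolysis list 0.04 and −0.41. Without the complete library labelled knockout of batch 2 the histone and hypoxia lists changed direction (adjusted p = 0.449 and 0.147) and the glycolysis and AP-1 calls were lost (0.604 and 0.129), and without that of batch 1 the calls of ribosomal proteins (0.873), p53 targets (0.819), glutathione metabolism (0.535), mitosis (0.106), proline synthesis (0.106), AP-1 genes (0.0891) and DNA replication (0.0677) were lost. Without the serine/glycine-free library labelled knockout of batch 1, 6 calls were lost (adjusted p 0.0614 to 0.101), and without that of batch 2, 8 were (0.0887 to 0.602). Over all alternatives the glutathione call was lost in 13 of 23, the AP-1 call in 9, and the ribosomal call in 7 with its direction changed in 1 more. Over all genes limma called 2 genes higher, SNORD54 and AL034400.1, and 1 lower, RNU6-1201P, each listed at 0 in both libraries of 1 group, with 1006 at an unadjusted p under 0.05.

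**Figure D2:**
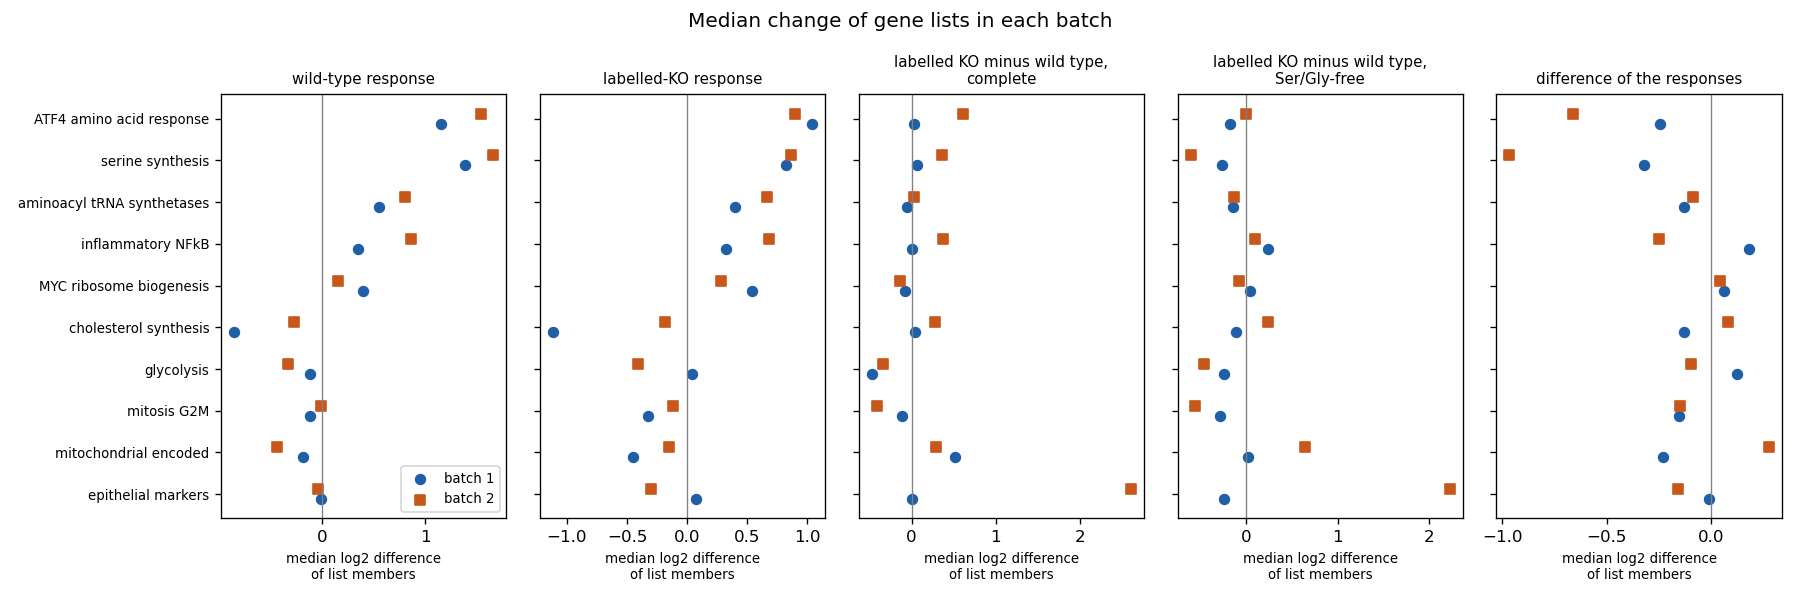
Median log2 difference of the members of 10 gene lists in each of the 5 comparisons, with batch 1 as circles and batch 2 as squares; the grey line marks 0. The ATF4 list lies at 1.15 and 1.54 in the wild-type response of batches 1 and 2, and the epithelial list at 0 and 2.60 in the genotype comparison in complete medium.

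The third comparison sets cells labelled knockout against wild type in complete medium. Glycolysis genes were lower as a group in the cells labelled knockout (median −0.44; batches −0.47 and −0.33), with 17 of 20 lower in both batches; PGK1 stood at 348 FPKM in wild type and 207 in the library labelled knockout in batch 1, and at 972 and 601 in batch 2. Mitosis genes (−0.28) and nucleotide synthesis genes (−0.26) were also lower, and mitochondrially encoded genes were higher (0.37; 11 of 14 in both batches). TYMS, thymidylate synthase, had a log2 fold change of −1.26 ± 0.19 (adjusted p = 0.832 over all genes). Camera gave adjusted p between 3.90e-06 and 0.00453 for these 4 lists, and adjusted p = 0.825 for each with an estimated correlation. The calls of glycolysis (adjusted p = 0.0595 without the library labelled knockout of batch 1), mitosis (0.480 without that of batch 2) and nucleotide synthesis (0.0616 without that of batch 2 and 0.299 without the wild-type library of batch 2) rested on single libraries.

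Mesenchymal markers were not called as a group (batch medians 0.10 and −0.21, camera adjusted p = 0.692). Epithelial markers were called higher (median 1.29), and the batches differed. The list stood at a median of 0 in batch 1 and 2.60 in batch 2, where CDH1, E-cadherin, was at 0.541 FPKM in wild type and 60.0 in the library labelled knockout and VIM, vimentin, at 598 and 118. The ATF4 list was also called higher (0.27; batches 0.03 and 0.61), as was amino acid transport (0.27; batches −0.000151 and 0.44). DNA replication (−0.22), histones (−0.39; batches −0.03 and −0.66) and hypoxia genes (−0.31; batches −0.74 and 0.16) were called lower. With an estimated correlation the adjusted p of these lists was 0.825 to 0.868, and without both batch 2 libraries labelled knockout, an alternative chosen after seeing the data, the epithelial list went the other way (adjusted p = 0.454). Without the complete library labelled knockout of batch 2 the calls of the epithelial (0.484), ATF4 (0.207), transport (0.469) and DNA replication lists (0.298) were lost and the histone list changed direction (0.836), without the wild-type complete library of batch 2 the same 5 lists missed the threshold (0.0687 to 0.887), and the hypoxia list changed direction without the complete library labelled knockout of batch 1 (0.283). The transport and hypoxia calls were also lost without any 1 of the serine/glycine-free libraries (0.0534 to 0.0686), and the hypoxia call without the wild-type complete library of batch 1 (0.674). Over all alternatives the transport call was lost in 14 of 21 and the hypoxia call in 11, with its direction changed in 1 more. Limma called 2 genes higher and 4 lower, none protein-coding, with 860 at an unadjusted p under 0.05. Fitting only the groups compared gave 0 of either, and no filter 0 higher and 1 lower.

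**Figure D3:**
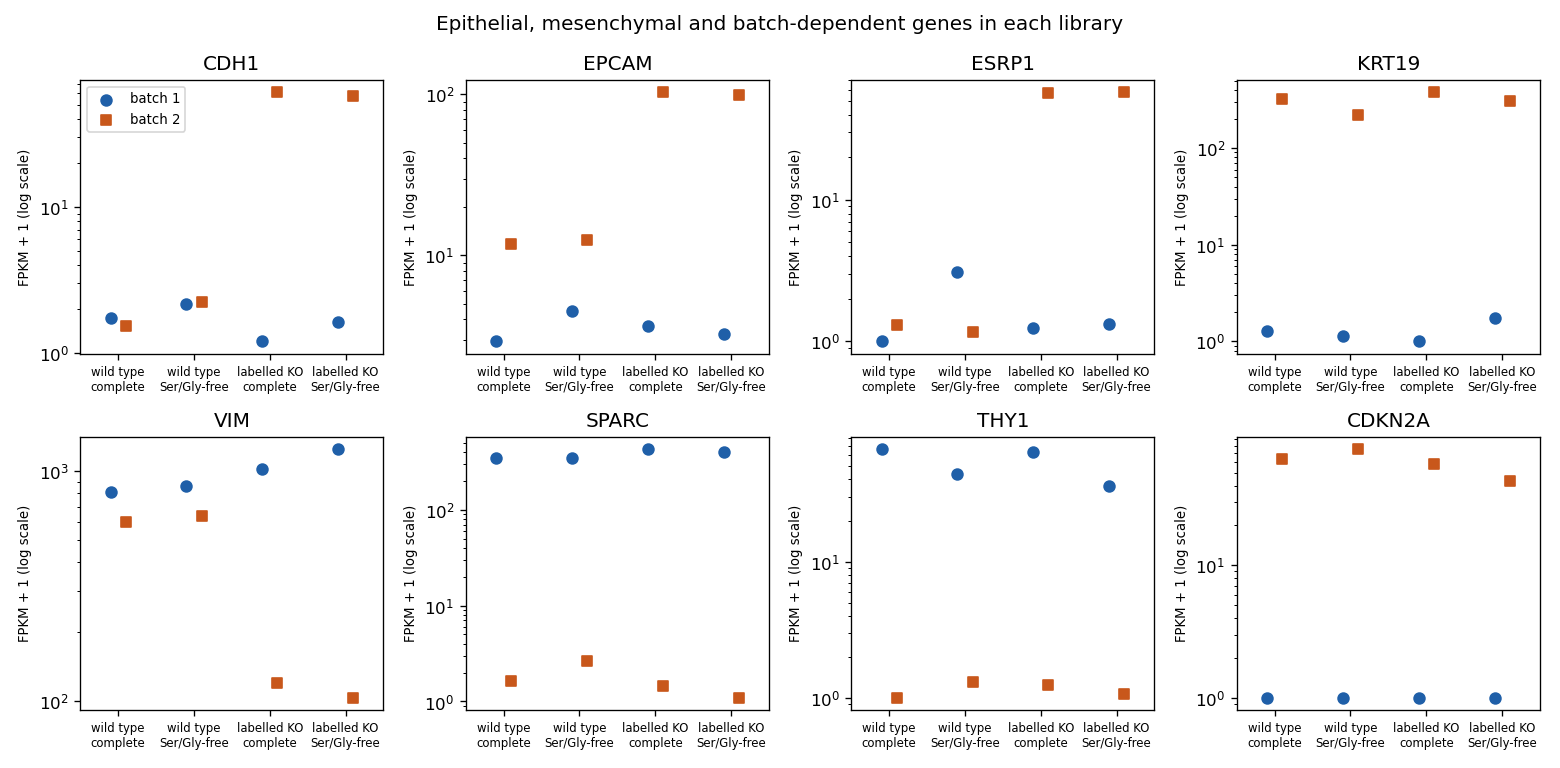
FPKM + 1 on a log axis for epithelial, mesenchymal and batch-dependent genes, 1 point per library, arranged by group with the batch as colour and shape. SPARC lies between 343 and 429 in batch 1 and at 1.66 or below in batch 2, and CDH1 and ESRP1 reach 55.8 or more only in the batch 2 libraries labelled knockout.

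The fourth comparison sets the genotypes side by side in serine/glycine-free medium. Mitosis genes were lower as a group in cells labelled knockout (median −0.41), with 21 of 25 lower in both batches; BUB1B had a log2 fold change of −0.75 ± 0.20 and NUSAP1 −0.72 ± 0.22. Glycolysis (−0.40) and DNA replication genes (−0.22; batches 0.03 and −0.32) were also lower and mitochondrially encoded genes higher (0.30; batches 0.02 and 0.64). PSPH, which passed when adjusted over the list alone but not over all genes, had −0.70 ± 0.18. PHGDH had −0.34 ± 0.24 and PSAT1 −0.15 ± 0.27. Over the alternatives PSPH lay between −0.82 and −0.51, PHGDH between −0.70 and 0.0120 and PSAT1 between −0.43 and 0.00201. Epithelial markers (median 1.05; batches −0.24 and 2.23) and interferon-stimulated genes (0.52; batches −0.39 and 1.29) were called higher, with opposite signs in the 2 batches. Camera gave adjusted p between 5.73e-08 and 0.0306 for these 6 lists, and adjusted p of 0.873 to 0.894 with an estimated correlation. Without the serine/glycine-free library labelled knockout of batch 2 the calls of the epithelial (0.0987), glycolysis (0.113) and DNA replication lists (0.485) were lost and the interferon list changed direction (0.596), and without the wild-type serine/glycine-free library of batch 2 those of the epithelial (0.378), DNA replication (0.234) and interferon lists (0.921) were lost. The DNA replication call was lost in 9 of 21 alternatives, with adjusted p up to 0.979. Limma called 2 genes higher and 7 lower, none protein-coding, with 1055 at an unadjusted p under 0.05. Fitting only the groups compared gave 2 higher and 1 lower, and the stricter filter 2 higher and 3 lower.

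The fifth comparison asks whether the response itself differed with the genotype label. The ATF4 list had a smaller response in cells labelled knockout, with a median difference of −0.44 (batches −0.24 and −0.66); 24 of 37 members were smaller in both batches and 2 larger. The call was lost with an estimated correlation (camera adjusted p = 0.994), and the batch 2 libraries labelled knockout, behind the larger difference, are those with epithelial genes higher (median 2.60 in complete medium). In serine/glycine-free medium itself the list was not called between genotypes (median −0.05; batches −0.18 and −0.00372; camera adjusted p = 0.439), while in complete medium its batch medians were 0.03 and 0.61 in cells labelled knockout against wild type. TRIB3 differed by −0.94 ± 0.45, NUPR1 by −0.88 ± 0.42, CEBPB by −0.67 ± 0.31 and XPOT by −0.51 ± 0.23, none passing over the list alone. The 3 serine synthesis genes were each smaller in both batches, PSAT1 by −0.73 ± 0.38, PHGDH by −0.61 ± 0.33 and PSPH by −0.49 ± 0.26. Mitosis genes, at −0.09 in wild type and −0.18 in cells labelled knockout, had a median difference of −0.19 and were lower in the cells labelled knockout in both batches for 21 of 25.

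Camera gave adjusted p = 8.70e-07, 0.00667 and 0.0364 for these 3 lists, and adjusted p = 0.994 for each with an estimated correlation. The ATF4 call was lost without the wild-type complete library of batch 2 (adjusted p = 0.123). The serine synthesis call was lost without that library (0.0703), the wild-type serine/glycine-free library of batch 2 (0.161) or the serine/glycine-free library labelled knockout of batch 2 (0.0747), and the mitosis call without any of these 3, the wild-type complete library of batch 1 or the complete library labelled knockout of batch 1 (0.0663 to 0.990). Of 22 alternatives the mitosis call was lost in 9, the serine synthesis call in 5 and the ATF4 call in 2. Limma called the difference positive for 5 genes and negative for 6, none protein-coding. With a pseudocount of 0.1, no filter, the stricter filter or no replicate block it called 2 and 1. An unadjusted p under 0.05 was reached by 276 genes, fewer than the 899.7 expected by chance. The fit leaves any genotype difference that varies with batch in its spread, which can widen the errors here and in the responses of each genotype. The low number is therefore no evidence that the responses were alike.

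Across genes the log2 fold changes of the 2 batches correlated weakly, at Pearson r = 0.128 for the wild-type response, 0.140 for the response of cells labelled knockout, 0.0244 and 0.0464 for the genotype comparisons in complete and serine/glycine-free medium and 0.0849 for the difference of responses. Genes higher in wild type by a log2 fold change of 1 or more in batch 1 (782 genes) had a median of 0.02 in wild type and 0.04 in cells labelled knockout in batch 2. The 589 genes chosen in batch 2 had medians of 0.30 and 0.18 in batch 1. Genes chosen as lower (592 in batch 1 and 390 in batch 2) had medians of 0 in both genotypes in the other batch. With protein-coding genes only, chosen after seeing the data, the medians of genes chosen as higher in batch 1 were 0.39 and 0.30. Those of genes chosen as lower in either batch were then below 0 in both genotypes.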

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

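The tests on the short RNAs were set up after the calls were seen and before their own outcomes, and the reassignment within genes was added after another version had been run. The responses of the 2 genotypes differed, by the test of the difference itself, for 11 RNA genes and, by camera with its preset correlation alone, 3 gene lists. With an estimated correlation none of the 3 lists was called (adjusted p = 0.994).

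The 11 genes are RNAs listed at 0 in at least 4 of the 8 libraries, and their fitted log2 differences of the responses (KO minus WT) depend on the pseudocount and are no bounds. They were positive for SNORD54 (21.52), AL034400.1 (9.11), U3 (6.37), U6 (5.64) and AC092964.1 (4.80), and negative for RNU6-1201P (−11.58), AC118344.1 (−7.78), Y_RNA on the X chromosome (−6.32), Y_RNA on chromosome 19 (−5.78), RNU6-1024P (−5.39) and AC079781.5 (−4.34). SNORD54, a box C/D small nucleolar RNA, was at 2458 and 2023 FPKM in wild-type complete medium and 2146 and 845 in the serine/glycine-free libraries labelled knockout, and listed at 0 in the other 4. AC079781.5 is a pseudogene whose deposited locus, chromosome 7 from 97481430 to 97501854, is also that of ASNS. Over the alternatives SNORD54 kept its call in 19 of 19 and AL034400.1 and RNU6-1201P in 18 of 19. Each of the other genes lost it in 12 to 15 of 18 or 19.

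Of the 14 genes called in any comparison, 9 are noncoding RNAs with transcripts under 300 bases, which gave 28 calls over the 5 comparisons. Exact zeros in at least 2 libraries were present in 100% of these 9, against 62.1% of all 738 such genes tested. The 9 stood out by being listed at 0 in both libraries of a group, so this share restates that pattern. Reassigning each gene's own 4 batch 2 values to the libraries at random gave as many calls in 22 of 100 draws (22%; median 23, highest 50), so chance coincidence of which libraries hold a read could account for their number. An earlier version that gave each gene the batch 2 values of another gene reached at most 5 calls, as many as observed in 0% of 100 draws; it decides nothing, because a read is worth a different FPKM in each gene and the swap adds spread by itself. The genotype stays among the open explanations for single RNAs, which were not tested 1 by 1.

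The lists were the ATF4 amino acid response (median difference −0.44), serine synthesis (−0.61) and mitosis (−0.19), the first pair with a smaller rise and mitosis with a more negative median in cells labelled knockout. The ATF4 list had genotype medians of 0.03 and 0.61 in complete medium of batches 1 and 2 and was not called in serine/glycine-free medium (median −0.05, camera adjusted p = 0.439). The difference in ATF3 genotype stays among the untested explanations. Another clone or cell population in the batch 2 libraries labelled knockout also stays open; there the epithelial list had genotype medians of 2.60 and 2.23 in complete and serine/glycine-free medium and 21 protein-coding genes were on in 1 genotype and off in the other, against 0 in batch 1. Without both these libraries, an alternative chosen after seeing the data, the adjusted p of the ATF4, serine synthesis and mitosis lists was 0.0102, 0.0597 and 0.00377.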

How the results depend on the processing

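The alternatives with protein-coding genes only, with a replicate block per genotype and batch, or without both KO libraries of batch 2 were chosen after seeing the data; WT and KO stand for the labels and the replicate number for the batch. Counts of genes and lists moved by over 1.5 times or to the other side of the threshold in 140 of 440 recomputed counts (88 smaller, 52 larger). For the genes the text draws on, 3299 recomputed values kept direction and side of the threshold. Of the others, 252 lost the call, 37 gained it and 15 changed direction. Many of these genes, such as ATF3 and the serine synthesis genes, had no call to lose. The 3299 therefore do not show how well calls held. For the called lists, 1048 recomputed values kept both, 207 lost the call and 21 changed direction. For the other genes the rule names 10118 kept both, 206 changed direction and 8 gained a call, and for lists not called 1853, 253 and 128. A fold change from 1 batch alone has no test. The cause of each change was not tested, except that fewer genes were tested under the filters and with protein-coding genes only, and fewer libraries entered where some were left out; where 1 library of a group remained it was assumed to vary like the other groups. Depth is unknown in reads, so no limit for a value of 0 is given. The planned count of the authors' own calls and the planned count test were not run, since the tables hold neither comparisons nor counts. Scaling moved the median of all genes by less than 0.1 in each comparison. The numbers pair the libraries, and the block is part of the fit.

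With an estimated correlation 0 lists were called in either direction in any comparison, with adjusted p = 0.179 for the ATF4 and serine synthesis lists in the wild-type response, 0.236 in the KO response and 0.994 for the difference of the responses. Fry called 5 lists higher in each response and 0 in the other comparisons.

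Gene counts of the WT response to serine/glycine-free medium were 7 higher and 3 lower. There were 1 lower with no filter, 2 higher and 1 lower with the stricter filter, 0 higher and 1 lower with only the groups compared and the replicate block, 11 higher with robust eBayes, 1 lower with protein-coding genes only, 5 lower with the replicate block per genotype and batch, and 52 higher and 6 lower with that block and protein-coding genes only. Without both KO libraries of batch 2, which left 1 library in each KO group, fewer genes were called in both directions. With protein-coding genes only as well, more were called higher and fewer lower. Single omissions gave 6 (WT_SGfree replicate 1) to 11 higher (WT_complete replicate 1) and 2 (WT_SGfree replicate 2) to 9 lower (WT_complete replicate 2).

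Those of the KO response were 2 higher and 1 lower. There were 2 lower with median-of-ratios scaling, 3 lower without trend, 2 lower with robust eBayes, 1 higher and 0 lower with protein-coding genes only, 4 higher with the replicate block per genotype and batch, 15 higher with that block and protein-coding genes only, and 0 of either without both KO libraries of batch 2, also with protein-coding genes. Omitting single libraries gave 2 (KO_complete replicate 1) to 9 higher and 0 (KO_SGfree replicate 1) to 4 lower, most without WT_complete replicate 1.

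Those of KO against WT in complete medium were 2 higher and 4 lower. There was 1 higher with pseudocounts of 0.1 and 0.5 and with no replicate block, 0 higher and 1 lower with no filter, 1 higher and 2 lower with the stricter filter, 0 of either with only the groups compared and with protein-coding genes only, and 0 higher and 2 lower without both KO libraries of batch 2 (0 of either with protein-coding genes). Leaving out 1 library gave 1 (KO_complete replicate 1) to 7 higher (WT_complete replicate 1) and 1 (KO_complete replicate 1) to 8 lower (WT_complete replicate 2). In serine/glycine-free medium there were 2 higher and 7 lower, against 3 lower with the stricter filter, 1 lower with only the groups compared, 0 of either with protein-coding genes only and 0 of either without both KO libraries of batch 2, also with protein-coding genes. Leaving out 1 library gave 2 (KO_complete replicate 1) to 6 higher (WT_complete replicate 1) and 0 (KO_SGfree replicate 1) to 9 lower (KO_complete replicate 1).

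Those of the difference of the responses were 5 higher and 6 lower. There were 2 higher and 1 lower with a pseudocount of 0.1, no filter, the stricter filter or no replicate block, 0 of either with protein-coding genes only, also with the replicate block per genotype and batch, 3 higher with that block, and 1 higher and 0 lower without both KO libraries of batch 2 (0 of either with protein-coding genes). Leaving out 1 library gave 2 (KO_complete replicate 1) to 7 higher (WT_complete replicate 2) and 1 (KO_SGfree replicate 1) to 4 lower (WT_SGfree replicate 1).

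Leaving out 1 library gave 8 (KO_complete replicate 1) to 14 lists higher (WT_complete replicate 1) in the KO response, where 13 were called. It gave 1 (WT_complete replicate 2) to 8 higher (WT_complete replicate 1) and 3 (KO_complete replicate 2) to 5 lower in complete medium, where 4 and 6 were called, 1 (KO_SGfree replicate 2) to 5 higher (KO_SGfree replicate 1) and 3 to 5 lower (WT_SGfree replicate 1) in serine/glycine-free medium, where 3 and 3 were called, and 0 to 4 higher (KO_complete replicate 2) and 0 (WT_complete replicate 2) to 6 lower (KO_complete replicate 1) for the difference, where 0 and 3 were called. With no filter 6 lists were lower in serine/glycine-free medium, and with quantile normalization 3 were lower in complete medium and 5 for the difference. Without both KO libraries of batch 2 there were 2 lists higher in complete medium, 1 higher and 8 lower in serine/glycine-free medium and 3 higher for the difference; with protein-coding genes as well there were 2, then 9 lower, then 3 higher and 5 lower.

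For the difference of the responses, with single libraries left out, the adjusted p of the ATF4 list ranged from 5.23e-13 (without WT_complete replicate 1) to 0.123 (without WT_complete replicate 2) and that of serine synthesis from 0.00253 (without WT_SGfree replicate 1) to 0.161 (without WT_SGfree replicate 2). Over all alternatives that of serine synthesis ranged from 0.000584 to 0.994, with 0.0597 without both KO libraries of batch 2. Directions changed for ribosomal proteins in the KO response with quantile normalization (0.266), and over single omissions for hypoxia genes in the WT response (9.68e-05 to 0.977), the KO response (2.15e-07 to 0.147) and complete medium (2.05e-08 to 0.674), histones in the KO response (4.88e-11 to 0.449) and complete medium (1.13e-09 to 0.836) and interferon genes in serine/glycine-free medium (1.19e-07 to 0.921). Without both KO libraries of batch 2, all genes then protein-coding genes, directions changed in the KO response for glycolysis (0.799, 0.789), histones (0.402, 0.397) and hypoxia genes (0.402, 0.268), in complete medium for the epithelial list (0.454, 0.390) and histones (0.737, 0.739), and in serine/glycine-free medium for the epithelial list (0.844, 0.820) and interferon genes, then called lower (0.0410, 0.0338).

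Among genes, ATF3 changed direction with single libraries left out, with log2 fold changes of −0.222 to 1.955 in the KO response, −0.0512 to 2.25 in complete medium, −0.51 to 1.67 in serine/glycine-free medium and −1.67 to 0.63 for the difference. In serine/glycine-free medium, with single libraries left out, PHGDH ranged from −0.70 to 0.0120 and PSAT1 from −0.31 to 0.00201; without both KO libraries of batch 2 PSAT1 had −0.43. Without both KO libraries of batch 2, also with protein-coding genes only, ATF3 had −0.77 in serine/glycine-free medium, PSPH 0.00479 and HIST1H4C 0.0292 in complete medium and HIST1H2AC −0.0116 in the KO response.

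The agreement of the 2 batches (Pearson r), in the order of the comparisons in the report, was 0.128, 0.140, 0.0244, 0.0464 and 0.0849. It was 0.0650, 0.0897, 0.00686, 0.0204 and 0.0425 with a pseudocount of 0.1 and 0.280, 0.238, −0.0270, 0.0155 and −0.0132 with protein-coding genes only. For the 2 responses and their difference it was 0.106, 0.123 and 0.0688 with a pseudocount of 0.5 and 0.0865, 0.0939 and 0.0534 with no filter.

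Medians in the other batch of genes chosen as higher in batch 1 were 0.34 in WT and 0.29 in KO with the stricter filter, and 0.39 and 0.30 with protein-coding genes only. For genes chosen as higher in batch 2 they were 0.0743 and 0 with no filter, 0.32 in KO with the stricter filter and 0.46 in KO with protein-coding genes only. For genes chosen as lower in batch 1 they were −0.0385 in WT and −0.0624 in KO for genes chosen at 0.58, −0.0333 and −0.0358 with quantile normalization, −0.12 and −0.17 with protein-coding genes only and −0.0480 in WT with the stricter filter. In KO they were −0.0257 and −0.0129 with pseudocounts of 0.1 and 0.5 and −0.0187 with median-of-ratios scaling. For genes chosen as lower in batch 2 they were −0.0434 in WT and −0.0553 in KO for genes chosen at 0.58, −0.17 and −0.0370 with protein-coding genes only, and −0.0102 in KO with a pseudocount of 0.1.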

Other observations

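The genes and tests of this part were chosen after the data were seen. Several metallothioneins, small proteins that bind zinc and copper, stood higher in serine/glycine-free medium in both genotypes. MT1X was at 12.6 FPKM in complete and 233 in serine/glycine-free medium in wild type of batch 1 and at 42.5 and 324 in batch 2; in libraries labelled knockout it was at 10.8 and 192 and at 15.4 and 292. Its log2 fold change was 3.50 ± 0.32 in wild type (limma adjusted p = 0.0545) and 4.10 ± 0.32 in cells labelled knockout (adjusted p = 0.0531). MT2A had 2.55 ± 0.49 and 3.54 ± 0.49. MT1E was abundant in batch 1 alone, from 70.0 to 1706 FPKM in wild type, and MT1F was listed at 0 in every batch 1 library and went from 8.51 to 63.3 in wild type of batch 2. Of the 5 members examined, 3 were higher in both batches in wild type and 4 in cells labelled knockout; MT1M went from 0.420 FPKM to a listed 0 in wild type of batch 1 and from 1.78 to 59.4 in batch 2. The fitted values of the 5 were positive in both genotypes, also under quantile and median-of-ratios scaling, and the set was not tested as a group.

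A set of 9 heat shock and chaperone genes, picked after their values were seen and not tested as a group, went the other way. All 9 were lower in serine/glycine-free medium in both genotypes and batches, with medians of −0.78 in wild type and −0.70 in cells labelled knockout, and stayed lower under both scalings. The set leaves out measured members such as HSPA13 and HSPA9, whose wild-type values were positive (0.74 ± 0.20 and 0.69 ± 0.14; adjusted p = 0.735 and 0.505). HSPA8, the constitutive HSC70 chaperone, was at 1080 FPKM in complete and 324 in serine/glycine-free medium in wild type of batch 1 and at 938 and 315 in batch 2, against 1041 and 632 and 784 and 489 in libraries labelled knockout. Its log2 fold change was −1.65 ± 0.16 in wild type (adjusted p = 0.0636) and −0.70 ± 0.16 in cells labelled knockout (adjusted p = 0.794), and the difference of 0.95 ± 0.23 did not pass. HSPA1A had −2.33 ± 0.36 and −2.05 ± 0.36.

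The 2 batches differed in protein-coding genes that were on in 1 and off in the other: 54 were at 10 FPKM or more in all 4 libraries of batch 1 and below 0.5 in all 4 of batch 2, among them THY1, and 32 the reverse, among them CDKN2A and TFF1. After correction of the batch difference for transcript length and GC content, 100% of these 86 genes kept a log2 difference above 3. The correction removes only a smooth trend over all genes, and these genes were chosen for a large difference, so this decides little. Cells of another type mixed into 1 batch would add genes in that batch alone, and the 32 genes of the smaller direction argue against that. Failed estimates listed at exactly 0 could account for few of them, since all 4 low values were exactly 0 in 12.8%. This cannot exclude estimates that leave a small value, as where reads are split with an overlapping gene. RAB5C, for example, was listed at 6.14e-06 FPKM in the serine/glycine-free library labelled knockout of batch 2. Different clones or populations of the named line, or another line in 1 batch, stay open, untested, since batch is not a group of the design, and with another line every n = 2 value of the report would span 2 lines.

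Epithelial genes stood higher in the batch 2 libraries labelled knockout. In complete medium the epithelial list's median log2 level was 2.94 in batch 2 wild type and 6.13 in the library labelled knockout. It was 0.56 in batch 1 wild type, so batch 2 wild type stood higher as well. KRT19 was at 321 and 216 FPKM in batch 2 wild type, 375 and 306 in libraries labelled knockout, and at most 0.741 in batch 1. CDH1, however, was at 0.541 and 1.23 in batch 2 wild type. A genotype effect alike in both batches is argued against, but not firmly, by the batch 1 median of 0 beside 2.60 in batch 2. The median absolute deviations (0.503 and 2.11) are spreads over the 16 members and give no error of either median. Each median rests on 1 library per genotype. The list's median log2 level in complete medium of batch 1 was low, 0.56 in wild type and 0.29 in the library labelled knockout. In complete medium 7 of the 16 members were higher in the libraries labelled knockout in both batches, and 0 were lower in both. Of the abundant members, KRT8 and KRT18 changed sign, with differences of −0.74 and −0.86 in batch 1 and 1.73 and 1.51 in batch 2. Epithelial cells mixed in at under 90% are argued against by 12 protein-coding genes at 10 FPKM or more in both wild-type libraries of batch 2 that lay below 10% of that in both libraries labelled knockout, against 2 in batch 1. Another clone or cell population under that label cannot be told apart from a genotype effect in batch 2: between genotypes 21 protein-coding genes were at 10 or more in 1 and below 0.5 in the other in batch 2, such as ESRP1, and 0 in batch 1, but each batch holds 1 set of cultures per genotype.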
